A study of Rattus norvegicus with 12 samples.

How the data were processed

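Rat primary nucleus pulposus cells were transduced with a control or a CBX4 adenovirus and then given TNF-α or not, in 4 groups with 12 samples at 48 h per the labels. Total RNA was extracted with Trizol and libraries were made with an mRNA-seq kit. The deposited tables hold 9 libraries of 3 groups; CBX4 vector without TNF-α is in none of the 4 tables used and was left out. All 9 were mapped to their group and replicate by column name, with 0 columns unmapped.

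The values are FPKM per gene and per transcript, made by the authors from reads aligned to rn6 before deposit; aligner, counting tool and test are not given in the sources used here. The deposited fold is the ratio of the group means of FPKM in the authors' tables (largest relative difference 5.2e-15), and the authors also give its log2. The p-value and q-value in the deposited tables are the authors' own, from a test that is not named. All 280 and 209 gene calls of the authors follow a p-value under 0.05 with an absolute log2 ratio of at least 1. NC_TNF values were the same in both gene files (largest difference 0), so 1 scale was used throughout. FPKM per library summed to 492537 to 512232, and the 10 highest genes took 12.2% to 15.0%. The spacing of low values implied a depth that differed by up to 1.40 times between libraries, on the assumption that 1 step is 1 fragment. Since 52.8% to 58.3% of low values lay within 0.05 steps of a multiple of 0.5 steps, against 20% by chance, whole reads were not recovered and no count model was used.

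Genes with a mean FPKM of at least 1 over the compared libraries were tested with limma 3.58.1 (R 4.3.3, with the package data.table, version 1.17.8) on log2(FPKM + 1), with a trend in the prior variance and only the compared pair of groups in the fit. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called rising or falling at an adjusted p under 0.05. The comparisons were NC_TNF against NC, OE_TNF against NC_TNF, OE_TNF against NC, and the overlap of the first pair. Reversal was compared with 100 simulations in which no gene changes and the NC_TNF arm is shared. Each comparison was also made per transcript.

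The labels do not say whether replicate numbers pair the samples. After removal of group means, libraries of the same number correlated at 0.388 to 0.743 and others at -0.637 to 0.181 across 12042 genes, and 9 of 9 libraries correlated best with their own number. The pairing is thus read from the data. Results are given without and with the number as a block. Simulated data with 200 changes were given the replicate differences and the blocked-fit spread of these libraries. A gain with the block was thus built in and does not show that the numbers pair the samples. There, recovery of a log2 change of 1 was 21%, 24% and 26% without the block and 93%, 96% and 85% with it in the order of the comparisons, at 0%, 1.89% and 0% wrong calls without and 5.45%, 9.43% and 5.29% with it.

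The fit, filter, thresholds, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. The 27 lists with 807 entries were written from general knowledge: NF-κB target genes, cytokines and chemokines, TNF receptor and IKK signalling components, matrix-degrading enzymes, protease inhibitors, cartilage and nucleus pulposus matrix, fibrous and interstitial matrix, senescence-associated genes, cell cycle and proliferation, Polycomb and SUMO components, TGF-β and BMP response, and 15 lists of other pathways and cell types. Some lists share members, such as Ccl2 and Csf2 among NF-κB target genes, cytokines and senescence-associated genes. Results of such lists are not independent of each other. The lists were tested with camera at a preset correlation of 0.01 and again with an estimated one. The estimated form rests on the few residual degrees of freedom of these libraries, so failing it does not show that correlation made a result. In OE_TNF against NC_TNF cartilage and nucleus pulposus matrix genes had an estimated correlation of -0.0371, below the preset. Their camera adjusted p still went from 0.00986 to 0.321. Other lists lay far above the preset. Cell cycle genes had estimates of 0.896, 0.752 and 0.943 in the order of the comparisons (with the block 0.842, 0.0565 and 0.944). Cholesterol synthesis genes had 0.891, 0.884 and 0.854 without the block. For such lists the camera p-values at the preset correlation may be far too small. Of the lists called at 0.05, only NF-κB target genes in NC_TNF against NC, and NF-κB target genes and cytokines in OE_TNF against NC, passed with an estimated correlation, and none did with the block, where the lowest adjusted p was 0.164, 0.526 and 0.243. Terms with 10 to 500 tested genes were tested with a one-sided Fisher exact test against all annotated tested genes. Genes named in the text are 24 chosen for the question (Krt19 and Nos2 were not found by symbol), the 8 rising and 8 falling called genes with the largest log2 change whose groups do not overlap, and in each list that passed or had at least 3 called members the 3 with the smallest adjusted p. Other genes are marked as chosen after their values were seen.

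Alternatives covered the pseudocount, the filter, the trend, scaling, all groups in 1 fit, the block, library weights, a fold threshold and each library left out.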

Results

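Nucleus pulposus cells, the resident cells of the gelatinous core of the intervertebral disc, were cultured from Sprague Dawley rats and transduced with a control adenovirus or with an adenovirus carrying CBX4, each with or without the inflammatory cytokine TNF-α. CBX4 is a chromobox protein of Polycomb repressive complexes and a SUMO ligase. The labels describe 4 groups of 3 samples, 12 in all, at 48 h. The values used here cover 9 of them: control vector (NC), control vector with TNF-α (NC_TNF) and CBX4 with TNF-α (OE_TNF), each with n = 3. CBX4 vector without the cytokine was not analysed here, so no effect of CBX4 in unstimulated cells is given. Per library, 11584 to 12170 of 20319 genes reached 1 FPKM, and 15.7% to 23.0% of genes were listed at 0. Read totals were not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are means ± SD over 3 libraries, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

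Cbx4 itself, which checks the labels, lay at 10.5 ± 3.04 FPKM in NC and 9.22 ± 2.85 in NC_TNF, and at 482, 740 and 3408 FPKM in OE_TNF replicates 1, 2 and 3. The gene (ENSRNOG00000046207, chromosome 10, 108190995 to 108196217 on the minus strand of rn6, 1 transcript of 5 exons) was 6.75 log2 units higher in OE_TNF than in NC_TNF (SE 0.70, limma adjusted p = 0.114), with complete separation of the groups. With the replicate number as a block the same difference passed (SE 0.43, adjusted p = 0.0352). Against NC, Cbx4 rose by 6.57 log2 units in both fits (adjusted p = 0.0290, blocked 0.0115). With TNF-α alone Cbx4 had a log2 change of -0.18, which did not pass (adjusted p = 1, blocked 0.189). It was lower in each replicate number, at 5.97, 10.3 and 11.3 FPKM in NC_TNF against 7.13, 11.3 and 13.0 in NC.

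Several genes by which nucleus pulposus tissue is recognised were at the floor in these cultures. Acan and Col2a1, the aggrecan core protein and the cartilage collagen chain, reached at most 0.0623 and 0.0137 FPKM in any library, and Krt18 at most 0.0914 FPKM. Sox9, the transcription factor that drives both matrix genes in cartilage, lay at 1.78 ± 0.498 FPKM in NC, 1.22 ± 0.224 in NC_TNF and 1.96 ± 0.827 in OE_TNF, and passed in no comparison. Fibrillar collagen was abundant, with Col1a1, chosen after its values were seen, at 3721 ± 1503 FPKM in NC. Of the macrophage and leukocyte markers 3 were measured with TNF-α (camera adjusted p = 0.450). Cd68, chosen after its values were seen, rose in the blocked fit (0.60, adjusted p = 0.0364). Of the endothelial markers 2 were measured, with no call (camera adjusted p = 0.503).

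The first comparison, NC_TNF against NC, asks what TNF-α did in control-vector cells. Several chemokine genes rose, as did Tnfaip3 and Nfkbia, which encode inhibitors of NF-κB, a transcription factor through which TNF-α signals. Cxcl2, a neutrophil-attracting chemokine, rose from 1.94 ± 1.30 to 161 ± 77.6 FPKM, a log2 change of 5.75 (SE 0.47, adjusted p = 0.0131). Cxcl3 rose by 4.92 (SE 0.40, adjusted p = 0.0128), the growth factor gene Csf2 by 3.92 (SE 0.29, adjusted p = 0.0103) and the membrane-bound chemokine Cx3cl1 by 3.28 (SE 0.25, adjusted p = 0.0107). Ccl2, which attracts monocytes, went from 873 ± 46.4 to 4148 ± 618 FPKM (2.24, SE 0.15, adjusted p = 0.00769). Tnfaip3, which encodes the ubiquitin-editing NF-κB inhibitor A20, rose by 2.81 (SE 0.18), the apoptosis inhibitor Birc3 by 2.45 (SE 0.16), and Nfkbia, the gene of IκBα, by 1.61 (SE 0.14, adjusted p = 0.0191). Of the 36 measured NF-κB target genes 35 were higher and 11 rose, 24 when adjusted over the list alone. The blocked fit called 28, and 31 over the list alone. Their median change was 1.24 (camera adjusted p = 2.5e-49; adjusted p = 0.0205 with an estimated correlation, 0.196 in the blocked fit). Of 25 cytokines and chemokines 6 rose and 14 adjusted over the list alone, with a median of 1.82 (camera adjusted p = 3.4e-31; adjusted p = 0.0503 with an estimated correlation). The blocked fit called 15 of them, and 20 over the list alone. It added Il6 (1.44, blocked adjusted p = 0.0449, unblocked 1, SE 0.24; 1.44, SE 0.25, 0.0513 with block and median-ratio scaling, where the SE was slightly larger). Ccl20 (4.56, blocked 0.0158) and Csf3 (3.76, blocked 0.00833) were also added, and were chosen after their values were seen. Ptgs2, the inducible cyclooxygenase gene, rose by 1.24 in the blocked fit (adjusted p = 0.0210, unblocked 0.471), as did Icam1 (0.45, blocked 0.0320) and the NF-κB subunit gene Rela (0.35, blocked 0.0472). Il1b and Tnf stayed at or under 2.29 and 1.49 FPKM in all libraries.

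Some genes for matrix-degrading enzymes rose, while most genes for fibrous matrix were lower and passed only with the replicate number as a block. Mmp10, a stromelysin gene, rose from 284 ± 43.1 to 2423 ± 439 FPKM (3.08, SE 0.19, adjusted p = 0.00769), and Plau, the urokinase gene, by 1.78 (SE 0.13, adjusted p = 0.0103). Mmp3, the other stromelysin gene, went from 1371 ± 492 to 10275 ± 3925 FPKM and was the top gene by FPKM in NC_TNF replicates 1 and 2. Its change of 2.90 passed in the blocked fit (SE 0.049, adjusted p = 0.000251) and not in the unblocked one (SE 0.41, adjusted p = 0.106). The collagenase genes Mmp13 (3.41, blocked adjusted p = 0.0167, unblocked 0.448) and Mmp1 (2.05, blocked 0.0103, unblocked 0.0747) behaved alike. Of 31 matrix-degrading enzymes 2 rose, 7 adjusted over the list alone, and 9 rose while 2 fell in the blocked fit (camera adjusted p = 0.00168; adjusted p = 0.0893 with an estimated correlation, and 0.0956 by camera with the block). The aggrecanase genes Adamts4 (0.53, adjusted p = 1, blocked 0.0674) and Adamts5 (-0.26, adjusted p = 1, blocked 0.644) and the inhibitor gene Timp1 (0.38, adjusted p = 0.765, blocked 0.0875) did not pass. Of 12 protease inhibitors 0 were called by limma without the block (3 at an unadjusted p under 0.05), and 3 rose and 3 fell with it (camera adjusted p = 0.199). Tgfb3, a growth factor gene that promotes matrix deposition, fell by 1.47 (SE 0.15, adjusted p = 0.0263), and Itga11, a collagen receptor gene, by 1.93 (SE 0.20, adjusted p = 0.0287). Of 37 fibrous and interstitial matrix genes 30 were lower, with a median of -0.38 (camera adjusted p = 1.2e-08; adjusted p = 0.187 with an estimated correlation). None of the 37 fell in the unblocked limma fit (10 at an unadjusted p under 0.05, 1 adjusted over the list alone), while 20 fell with the block, and 26 over the list alone. Among these were the crosslinking enzyme gene Loxl3 (-0.95, blocked adjusted p = 0.00890, unblocked 0.123), Col16a1 (-0.53, blocked 0.0233) and the microfibril gene Mfap5 (-0.63, blocked 0.0217). The main fibrillar collagen genes, chosen after their values were seen, fell with the block. Col3a1 went from 650 ± 304 to 165 ± 79.5 FPKM (-1.99, blocked SE 0.054, adjusted p = 0.00139, unblocked 0.490). Col1a2 changed by -0.89 (blocked adjusted p = 0.00887) and Col1a1 by -0.85 (blocked 0.0118). Of 18 cartilage and nucleus pulposus matrix genes 0 were called without the block (5 at an unadjusted p under 0.05) and 1 rose and 3 fell with it (camera adjusted p = 0.199).

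**Figure D1:**
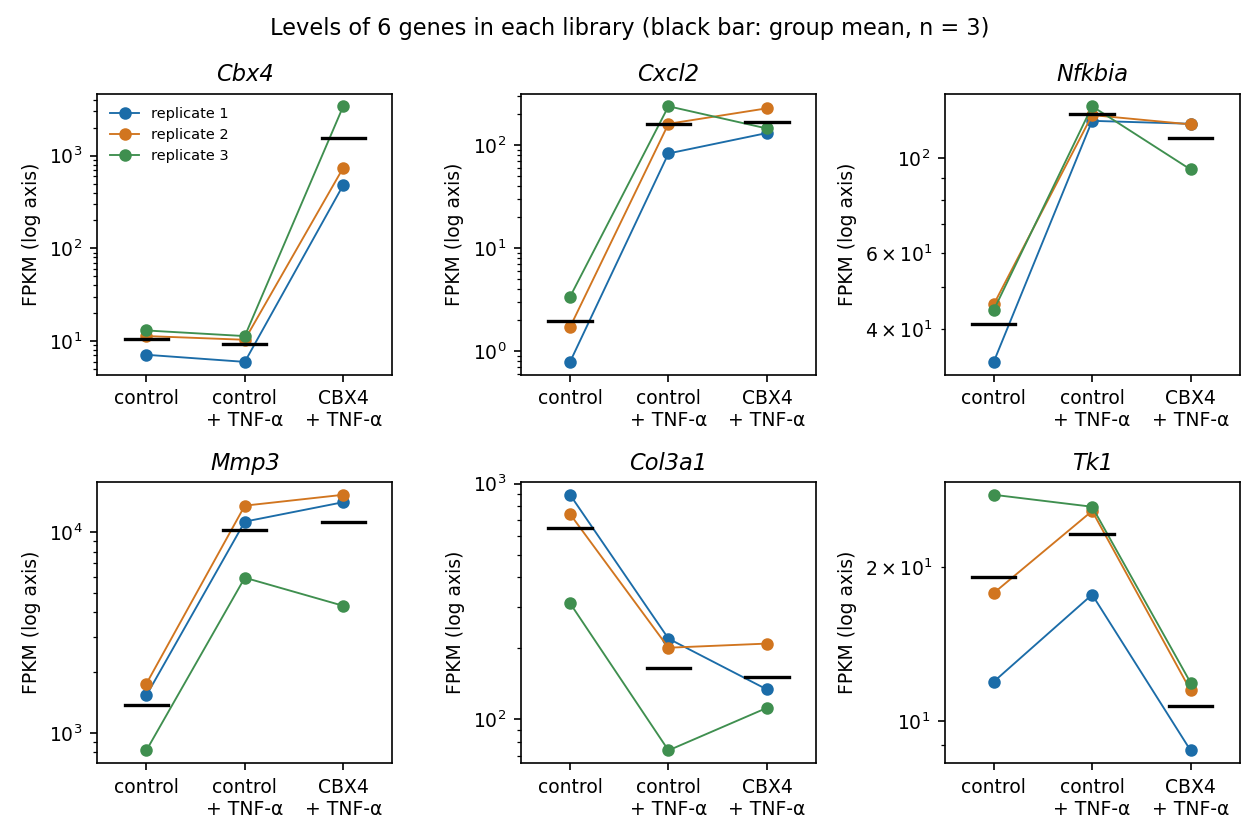
FPKM per library, on a log axis, of Cbx4, Cxcl2, Nfkbia, Mmp3, Col3a1 and Tk1 in NC, NC_TNF and OE_TNF, with points of 1 replicate number joined by lines and black bars at the group means. Col3a1 went from a mean of 650 FPKM in NC to 165 in NC_TNF and 152 in OE_TNF, and the lines of the 3 replicate numbers run nearly parallel from NC to NC_TNF.

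Most interferon response and senescence-associated genes were higher with TNF-α, and some of each passed, while the cell cycle inhibitors that mark senescent cells did not pass. Of 36 interferon response and antigen presentation genes 29 were higher, 0 passed in the unblocked limma fit (9 higher at an unadjusted p under 0.05, 4 adjusted over the list alone) and 12 rose with the block (camera adjusted p = 8.9e-09; adjusted p = 0.0503 with an estimated correlation). These included the proteasome activator gene Psme2 (0.65, blocked adjusted p = 0.0270), Gbp5 (1.04, blocked 0.0302) and the transcription factor gene Irf1 (1.20, blocked 0.0327). The TNF receptor and IKK signalling list shares Tnfaip3, Birc3, Tnip1 and Nfkbia, among others, with the NF-κB target list. Of its 35 measured components 5 rose (9 adjusted over the list alone). With the block 14 rose and 1 fell (camera adjusted p = 2.9e-11; adjusted p = 0.0503 with an estimated correlation). Of 43 senescence-associated genes 6 rose, 10 rising and 1 falling when adjusted over the list alone, and 15 rose and 5 fell with the block (camera adjusted p = 1.0e-11; adjusted p = 0.111 with an estimated correlation). The risen members included Mmp10, Ccl2 and Csf2, which also belong to the matrix-degrading or cytokine lists. The cell cycle inhibitors Cdkn1a (0.10, adjusted p = 1, blocked 0.312) and Cdkn2a (0.11, adjusted p = 1, blocked 0.724) and Tp53 (0.26, adjusted p = 1, blocked 0.149) did not pass. The replicate numbers differed in the cell cycle and proliferation list, whose median less that of all genes was 0.745 and 0.718 in numbers 1 and 2 and -0.212 in number 3, with 38 of 44 genes lower there. The list's pooled change had a median of 0.36 with 42 of 44 genes higher and 0 called by limma in either fit (0 at an unadjusted p under 0.05, 5 with the block; camera adjusted p = 0.000553; adjusted p = 0.687 with an estimated correlation).

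Of 23 genes of unfolded protein and amino acid stress 12 were higher and 11 lower with TNF-α, and 6 fell and 1 rose in the blocked fit. Among the fallen were Trib3, a pseudokinase gene, at -1.54 (blocked adjusted p = 0.0124) and Chac1, which degrades glutathione, at -1.02 (blocked 0.0289). The list had a median of 0.02 and a mean of -0.22 (camera downward, adjusted p = 0.0341, with the block 0.225; adjusted p = 0.648 with an estimated correlation), and the median's sign flipped under quantile normalization. Smooth muscle and contractile markers were lower in 12 of 14 (camera adjusted p = 0.0164; adjusted p = 0.557 with an estimated correlation), with Tagln falling by 0.46 in the blocked fit (adjusted p = 0.0343). Cholesterol synthesis genes were higher in 21 of 24 (camera adjusted p = 0.0341; adjusted p = 0.724 with an estimated correlation) and glycolysis and hypoxia genes in 23 of 30 (adjusted p = 0.0113; adjusted p = 0.423 with an estimated correlation), where the vasodilator peptide gene Adm rose by 1.21 (blocked adjusted p = 0.0256). Hox genes, which set position along the body axis, were lower in 17 of 20 (camera adjusted p = 0.0341, with the block 0.0543; adjusted p = 0.622 with an estimated correlation), and in the blocked fit Hoxc6 rose by 1.17 (adjusted p = 0.0129) and Hoxc12 fell by 0.70 (adjusted p = 0.0306). Camera gave an adjusted p of 0.275 for Polycomb components, 0.634 for SUMO pathway components, 0.691 for TGF-β and BMP response, 0.0718 for annulus, tendon and fibroblast markers and 0.169 for nucleus pulposus and notochord markers. For antioxidant enzymes it gave 0.750, for complement and acute-phase genes 0.0588, for immediate-early and heat-shock genes 0.241, for mitochondrially encoded genes 0.559 and for osteoblast and hypertrophy markers 0.701 (median -0.30, mean 0.52). The medians of antioxidant, complement and mitochondrially encoded genes changed sign under quantile normalization.

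Over all 12080 genes tested, limma called 21 rising and 3 falling with TNF-α (657 at an unadjusted p under 0.05), and 354 rising and 343 falling with the replicate number as a block. All 24 unblocked calls were among the latter. The groups did not overlap in 1213 genes, 10.0% against 10% by chance for exchangeable libraries. Libraries paired by number are not exchangeable, and the other 3 splits that part every pair gave 1.28% to 2.33%. A gene with a real effect seldom separates in a split that swaps a pair. Such shares, here and below, may therefore lie under the chance level. The annotation term TNF signaling pathway held 9 of the 20 annotated risen genes (expected 0.163, one-sided Fisher exact test, adjusted p = 3.2e-11) and the IL-17 signaling pathway 7 (expected 0.120, adjusted p = 1.4e-08). In all 19 terms passed. With the block 80 terms passed for rising genes, led by cytokine-cytokine receptor interaction (30 of 99, expected 2.98, Fisher exact test, adjusted p = 2.7e-19). For falling genes 33 passed, led by extracellular space (62 of 425, expected 12.1, adjusted p = 7.2e-24) and with ECM-receptor interaction (14 of 47, expected 1.34, adjusted p = 1.0e-08). The authors' deposited table called 192 genes up and 88 down, 280 in all. Of the 235 tested here, 24 and 194 were called without and with the block. The count of 24 fell to 14 without NC replicate 1, 8 without NC replicate 2, 9 without NC_TNF replicate 2 and 0 without NC_TNF replicate 1 (515 at an unadjusted p under 0.05), and the blocked count to 84 and 59 without replicate numbers 1 and 2.

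The second comparison, OE_TNF against NC_TNF, asks what CBX4 overexpression changed in stimulated cells. Proliferation genes were lower, and most acute-phase genes higher. Single genes of these lists passed only with the replicate number as a block. The lists passed by camera at the preset correlation and not with an estimated one, where so few libraries leave little power. For cell cycle genes the estimated correlation was 0.752 (0.0565 with the block) against the preset 0.01. Their unblocked camera p-value at the preset may thus be far too small. All 44 cell cycle and proliferation genes were lower in OE_TNF by their mean log2 change, with a median of -0.84 (camera adjusted p = 2.7e-12; adjusted p = 0.484 with an estimated correlation, 0.526 with the block). The thymidine salvage gene Tk1 went from 23.2 ± 4.81 to 10.7 ± 1.70 FPKM (-1.04, SE 0.20, adjusted p = 0.543; blocked SE 0.091, adjusted p = 0.0380). Tyms, the thymidylate synthase gene, changed by -1.11 (blocked adjusted p = 0.0380) and Cenpa, the centromeric histone gene, by -0.97 (blocked 0.0483). The proliferation marker Mki67 (-0.85, blocked 0.0483), the replication helicase gene Mcm6 (-1.08, blocked 0.0380) and the survivin gene Birc5 (-1.12, blocked 0.0380) also fell, and were chosen after their values were seen. In counts, 0 of the 44 fell in the unblocked limma fit (21 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) and 23 fell with the block (42 over the list alone). Median-ratio scaling moved the median of all genes from -0.10 to 0.01 and the list's median to -0.73. With scaling and block together 2 of the 44 fell, Tk1 and Tyms, and 41 adjusted over the list alone. Per replicate number the list median less that of all genes was -0.73, -0.79 and -0.67 in OE_TNF against NC_TNF, and 0.036, -0.0038 and -0.905 in OE_TNF against NC, where NC replicate 3 had the highest level of the 9 libraries.

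**Figure D2:**
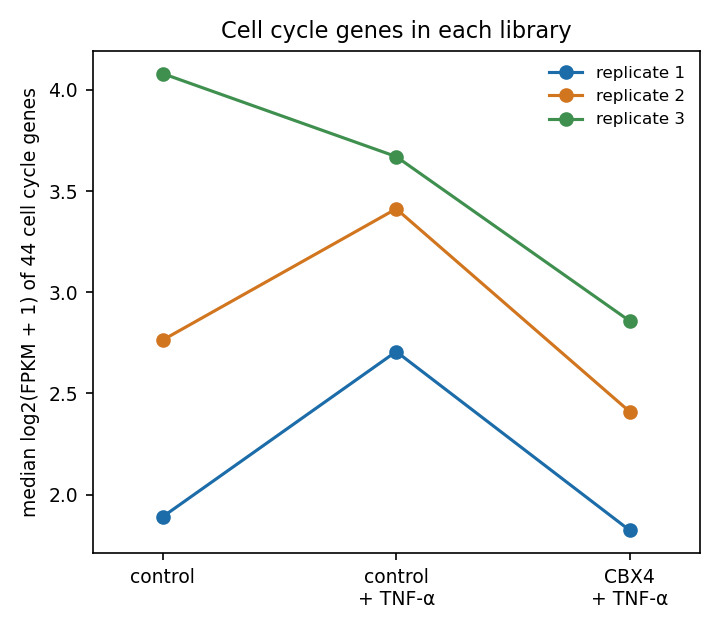
Median log2(FPKM + 1) of the 44 cell cycle and proliferation genes in each library of NC, NC_TNF and OE_TNF, with lines joining libraries of 1 replicate number. OE_TNF lies below NC_TNF in each replicate number, at 1.82, 2.41 and 2.86 against 2.71, 3.41 and 3.67, while NC spans 1.89 to 4.08.

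Of 16 complement and acute-phase genes 14 were higher with CBX4 (median 0.44, camera adjusted p = 1.7e-05; adjusted p = 0.367 with an estimated correlation). None rose in the unblocked limma fit (2 at an unadjusted p under 0.05), 3 rose with the block, and 6 adjusted over the list alone with the block. Haptoglobin, Hp, went from 31.5 ± 16.8 to 93.0 ± 28.6 FPKM (1.61, blocked adjusted p = 0.0380, unblocked 0.543), and the siderophore-binding protein gene Lcn2 rose by 0.90 (blocked 0.0483). The complement regulator Cd55, chosen after its values were seen, rose by 1.13 with block and scaling. Grem1, a secreted antagonist of bone morphogenetic proteins, went from 770 ± 156 to 1518 ± 182 FPKM (0.99, blocked adjusted p = 0.0483, unblocked 0.543). It was the 1 call among 33 TGF-β and BMP response genes, of which 24 were higher (camera adjusted p = 6.2e-06; adjusted p = 0.321 with an estimated correlation). Pax1, a transcription factor gene of the developing vertebral column, changed by -1.05 with TNF-α (blocked adjusted p = 0.0205) and by 1.01 with CBX4 (blocked 0.0483). Cytokines and chemokines were higher in 18 of 25 (median 0.49, camera adjusted p = 0.00138; adjusted p = 0.367 with an estimated correlation), and Il6 was the 1 that rose with the block (0.77, adjusted p = 0.0483, unblocked 0.644). After median-ratio scaling 4 of these blocked calls ended, although their changes were larger. Grem1 stood at 1.12 (SE 0.14, before 0.13, adjusted p = 0.0702), Lcn2 at 1.03 (SE 0.12, before 0.11, adjusted p = 0.0662), Pax1 at 1.13 (SE 0.11, before 0.12, adjusted p = 0.0627) and Il6 at 0.90 (SE 0.094, before 0.091, adjusted p = 0.0648). Their unadjusted p fell, so the adjusted values rose because fewer other genes had p-values as small. Genes at an unadjusted p under 0.05 went from 3248 to 2774. Among calls kept by the blocked fit after median-ratio scaling and chosen after their values were seen, the secreted hormone gene Stc1 changed by 1.95, the growth factor feedback gene Spry1 by 1.83 and the glutathione transferase gene Gsta1 by -1.68.

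Few inflammatory, matrix-degrading or senescence-associated genes passed with CBX4. Calls among NF-κB target and senescence-associated genes went both ways, while the 1 matrix-degrading call rose. Of 36 NF-κB target genes 0 were called without the block (4 at an unadjusted p under 0.05) and with it Il6 rose and Irf1 fell. The list's median was -0.04 and its direction flipped to 0.09 after median-ratio scaling, but relative to the median of all genes it lay higher both times, by 0.06 and 0.07 (mean -0.01, camera upward, adjusted p = 0.137 with the block). Nfkbia changed by -0.19 (adjusted p = 0.608, blocked 0.345), Ccl2 by 0.25 (adjusted p = 0.711, blocked 0.322), Cxcl1 by 0.77 (adjusted p = 0.543, blocked 0.0734) and Ptgs2 by 0.67 (adjusted p = 0.567, blocked 0.0815). Of 30 matrix-degrading enzymes 0 were called without the block (0 at an unadjusted p under 0.05) and 1 rose with it. Their median of -0.10 flipped to 0.01 after median-ratio scaling, the median of all genes both times (camera adjusted p = 0.431). The risen gene was Adamts1, chosen after its values were seen (1.27, blocked adjusted p = 0.0483). It did not pass with block and median-ratio scaling (1.41, adjusted p = 0.0694). Mmp3 lay at 11274 ± 6071 FPKM against 10275 ± 3925 (0.01, adjusted p = 0.996, blocked 0.975) and Mmp13 at 557 ± 112 against 683 ± 455 (-0.12, adjusted p = 0.933, blocked 0.769). Adamts5 (1.15, adjusted p = 0.543, blocked 0.0994) and Timp1 (0.20, adjusted p = 0.671, blocked 0.283) did not pass. Of 44 senescence-associated genes 0 were called without the block (7 at an unadjusted p under 0.05). With it 1 rose and 2 fell (median 0.03, mean -0.04, camera adjusted p = 0.109). Il6 rose, while Lmnb1 (-1.04, blocked adjusted p = 0.0483) and Gdf15 (-1.32, blocked 0.0483), chosen after their values were seen, fell. After median-ratio scaling neither passed (blocked 0.0702 and 0.0706). Members were not sorted by their direction in senescent cells, so these counts and the median do not measure senescence. Tp53 (-0.54, adjusted p = 0.543, blocked 0.0561), Cdkn1a (-0.17, adjusted p = 0.849, blocked 0.242) and Cdkn2a (-0.41, adjusted p = 0.597, blocked 0.135) did not pass. The TNF receptor and IKK signalling list had a median of -0.14 (camera adjusted p = 0.431, 1 of 35 falling with the block).

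**Figure D3:**
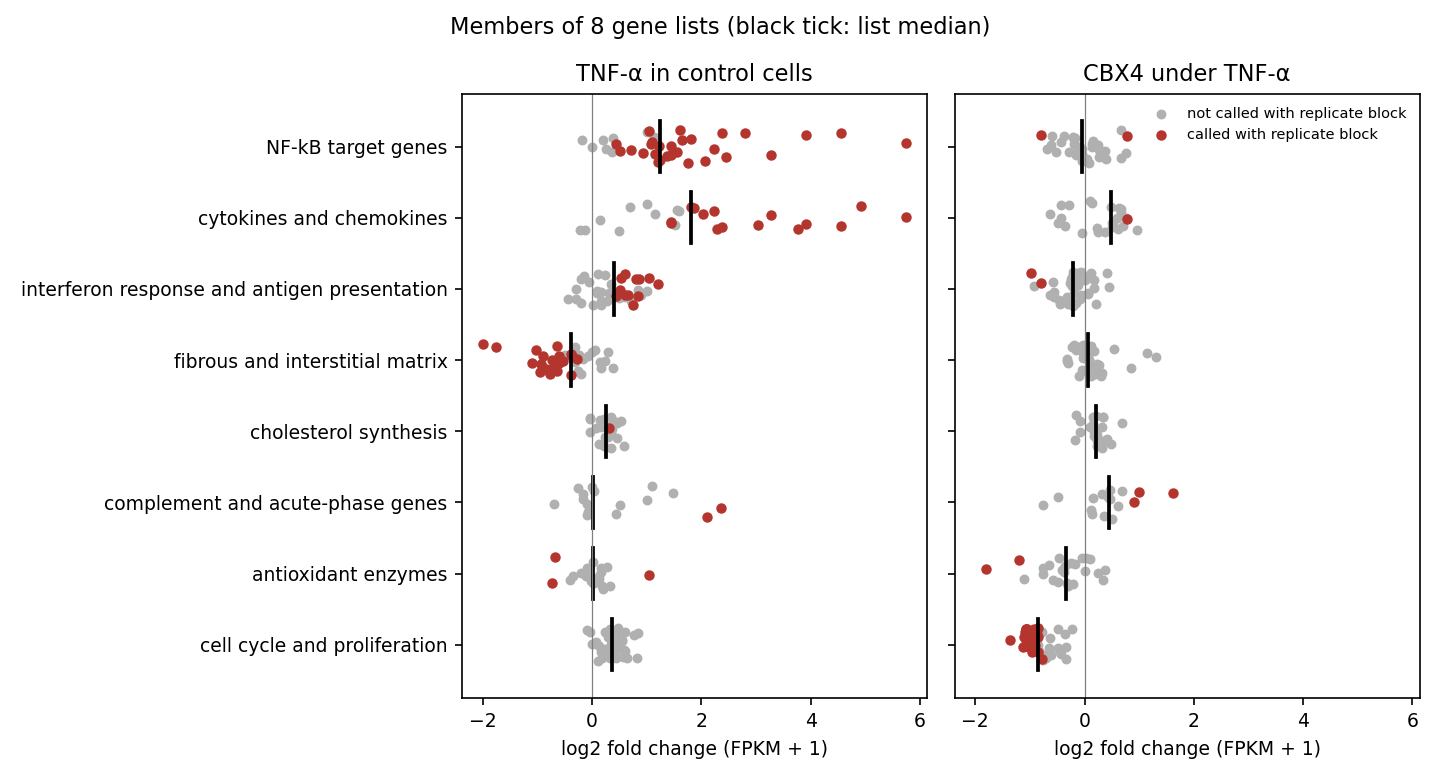
Log2 changes of the measured members of 8 gene lists in NC_TNF against NC and in OE_TNF against NC_TNF, with red points for genes called with the replicate number as a block and a black tick at each list's median. NF-κB target genes have medians of 1.24 and -0.04 and cell cycle genes of 0.36 and -0.84.

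Among the other lists with CBX4, camera called several higher, and none of these passed with an estimated correlation, where the lowest adjusted p was 0.321. Unfolded protein and amino acid stress genes had a median of 0.40 (camera adjusted p = 0.000188; adjusted p = 0.484 with an estimated correlation), cholesterol synthesis genes 0.22 (adjusted p = 0.000660; adjusted p = 0.612 with an estimated correlation) and annulus, tendon and fibroblast markers 0.16 (adjusted p = 0.00101; adjusted p = 0.321 with an estimated correlation). Cartilage and nucleus pulposus matrix genes were higher in 14 of 18 (camera adjusted p = 0.00986; adjusted p = 0.321 with an estimated correlation) and fibrous matrix genes in 24 of 37 (adjusted p = 0.00631; adjusted p = 0.554 with an estimated correlation). Col3a1, chosen after its values were seen, stayed at 152 ± 51.2 FPKM (-0.02, adjusted p = 0.990, blocked 0.965). Protease inhibitors (0.0302; 0.367 with an estimated correlation), Hox genes (0.0316; 0.441) and nucleus pulposus and notochord markers (0.0467; 0.367) were also called higher by camera. Antioxidant enzymes were lower in 18 of 24 (adjusted p = 0.0662, with the block 0.0282; adjusted p = 0.526 with an estimated correlation and the block). Not called were Polycomb components (0.551), SUMO components (0.431), glycolysis and hypoxia genes (0.0823 with the block), immediate-early and heat-shock genes (0.810), interferon response genes (0.496), mitochondrially encoded genes (0.823), osteoblast and hypertrophy markers (0.149), smooth muscle markers (0.866), endothelial markers (0.431) and macrophage markers (0.708). The medians of the Polycomb, glycolysis and mitochondrially encoded lists changed sign after median-ratio scaling, as the median of all genes did (-0.10 to 0.01).

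Over all 12006 genes tested, limma called 1 rising and 1 falling with CBX4 (1031 at an unadjusted p under 0.05), and 32 rising and 142 falling with the block. Median-ratio scaling of the blocked fit gave 15 rising and 9 falling, and quantile normalization 2 and 1. The falling gene was Wdr77, listed at 0 in each NC and OE_TNF library and at 4.56, 5.15 and 5.27 FPKM in NC_TNF (adjusted p = 0.00962, blocked 0.0286). The rising one was AABR07072266, chosen after its values were seen, at 0.0376 ± 0.0651 FPKM in NC_TNF and 8.26 ± 1.09 in OE_TNF (adjusted p = 0.00617, blocked 0.0130). The groups did not overlap in 2167 genes, 18.0% against 10% by chance for exchangeable libraries and 2.25% to 3.79% in the other 3 splits that part every pair. With the block 31 terms passed for falling genes, led by cell division (15 of 156, expected 1.97, Fisher exact test, adjusted p = 4.2e-06). None of 1973 terms passed for the 29 annotated rising genes. The authors' deposited table called 59 genes up and 150 down, 209 in all. Of the 188 tested here, 2 and 78 were called without and with the block. The count of 2 became 0 without NC_TNF replicate 1 or OE_TNF replicates 1 or 2, 1 without NC_TNF replicate 3, and 5 without NC_TNF replicate 2 or OE_TNF replicate 3, and the blocked count was 1, 41 and 18 without replicate numbers 1, 2 and 3.

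The reversal comparison asks how many changes with TNF-α were opposed with CBX4. The 21 genes that rose with TNF-α had a median change of -0.10 with CBX4, which equals the median of all genes. Of the 21, only Wdr77 was called lower in OE_TNF, where it is listed at 0 in each library, and 0 genes were opposed without genes listed at 0. With the block, of 354 genes that rose with TNF-α 11 fell and 3 rose with CBX4, at a median of -0.10, again that of all genes. Of the 334 fallen genes tested in both, 1 rose and 2 fell. By sign alone 232 were higher and 102 lower with CBX4, at a median of 0.13, above the -0.10 of all genes. Such a shift goes in the opposed direction, but the shared NC_TNF libraries alone could also give it. Over all genes 59.4% had opposite signs in both comparisons, against 66.8% (65.7% to 67.7%) in 100 simulations with no effect and a shared NC_TNF arm. Independent lists of these sizes would share 4.22 genes rising then falling and 0.814 falling then rising, and 0.863 and 3.99 for the same directions. Irf1 was among those that rose with TNF-α and fell with CBX4 in the blocked fit (1.20 and -0.80, blocked adjusted p = 0.0327 and 0.0483), as was Psmb10, an immunoproteasome subunit gene chosen after its values were seen (0.87 and -0.98, blocked 0.0176 and 0.0458). With median-ratio scaling and the block the opposed genes went from 12 to 2, and neither gene was among the 2. Irf1 then changed with CBX4 by -0.68 (SE 0.089, before scaling 0.095, adjusted p = 0.0702) and Psmb10 by -0.86 (SE 0.0996 in both, adjusted p = 0.0694). Across 11898 genes, which are not independent replicates, both log2 changes correlated at -0.245, while libraries with no effect sharing the NC_TNF arm gave -0.509 on average in 100 simulations (-0.576 to -0.443). Any effects in the real libraries widen the spread of the changes, which the simulations lack. Neither this correlation nor the share of opposite signs can therefore be read as less reversal than without effects. The covariance was -0.0301 against a simulated -0.0164 (-0.0210 to -0.0130), a difference of -0.0137. It ranged from -0.0146 without NC replicate 2 to -0.0784 without NC_TNF replicate 2. The 100 simulations called 0 genes opposed in either fit, against 1 and 12 here, but without effects few genes could pass in both comparisons. The 3 NC_TNF libraries could not be divided into parts of at least 2, so part of the overlap in calls may come from the shared arm.

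The third comparison, OE_TNF against NC, sets stimulated CBX4 cells beside unstimulated control cells. NF-κB target genes and chemokines remained far above the unstimulated level. Cxcl2 was 5.89 log2 units higher (SE 0.36, adjusted p = 0.00586), Cxcl3 5.55 (SE 0.40, adjusted p = 0.00765), Csf2 3.63 (SE 0.25, adjusted p = 0.00602), Ccl7 2.96 (SE 0.27, adjusted p = 0.0204), Tnfaip3 2.71 (SE 0.18, adjusted p = 0.00602) and Nfkbia 1.42 (SE 0.17, adjusted p = 0.0443). Of 35 NF-κB target genes 9 rose and 27 adjusted over the list alone, 23 with the block (median 1.38, camera adjusted p = 7.7e-39; adjusted p = 0.0472 with an estimated correlation, 0.243 with the block). Of 24 cytokines and chemokines 6 rose and 19 adjusted over the list alone, 15 with the block (median 2.20, camera adjusted p = 1.7e-32; adjusted p = 0.0472 with an estimated correlation). Of 30 matrix-degrading enzymes 0 rose without the block (9 at an unadjusted p under 0.05, 7 adjusted over the list alone) and 6 with it, among them Mmp9 (3.50, blocked adjusted p = 0.0241), Mmp10 (2.80, blocked 0.0242), Mmp3 (2.91, blocked 0.0115, unblocked 0.144) and Adamts5 (0.90, blocked 0.0240). For the list camera gave an adjusted p of 0.000539, and 0.0850 with an estimated correlation. Cyp7b1, an oxysterol hydroxylase gene, rose by 3.31 (SE 0.33, adjusted p = 0.0250), and Loxl3 fell by 1.24 (SE 0.13, adjusted p = 0.0260). Gns, a lysosomal sulfatase gene, was called falling (adjusted p = 0.00602) with values of 51.2, 19.7 and 38.7 FPKM in NC and listed at 0 in each OE_TNF library, and at 48.4, 0 and 0 in NC_TNF. A second entry of the same symbol did not pass (-0.01, adjusted p = 0.985).

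Cholesterol synthesis genes were higher in OE_TNF than in NC in 24 of 24, and in 21 of 24 in NC_TNF (OE_TNF median 0.48, camera adjusted p = 4.5e-07; adjusted p = 0.497 with an estimated correlation), with Mvd (0.79, blocked adjusted p = 0.0284) and Fdps (0.64, blocked 0.0489) rising in the blocked fit. Complement and acute-phase genes were higher in 15 of 17 (camera adjusted p = 2.7e-05; adjusted p = 0.417 with an estimated correlation), with the complement factor gene Cfb at 2.59 (blocked adjusted p = 0.0157), Lcn2 at 2.39 (blocked 0.0432) and Hp at 2.62 (SE 0.43, blocked 0.0489; 2.75, SE 0.43, 0.0517 after median-ratio scaling, as fewer genes had a smaller p). Grem1 rose by 1.18 with the block (adjusted p = 0.0157, unblocked 0.0514), among TGF-β and BMP response genes with a camera adjusted p of 0.00122 (0.0850 with an estimated correlation). Senescence-associated genes had 5 rising, and 10 rising and 4 falling with the block (camera adjusted p = 2.0e-09; adjusted p = 0.124 with an estimated correlation). TNF receptor and IKK signalling components had a median of -0.01, which flipped to 0.11 after median-ratio scaling (0.11 and 0.12 above the median of all genes), and a mean of 0.33 (camera adjusted p = 3.7e-06; adjusted p = 0.0661 with an estimated correlation). Interferon response genes (camera adjusted p = 3.1e-05; adjusted p = 0.395 with an estimated correlation), glycolysis and hypoxia genes (0.000539; 0.433) and protease inhibitors (0.0114; 0.157) were also called higher. Cell cycle genes were lower in 43 of 44 (adjusted p = 0.169, with the block 0.00144; 0.757 with an estimated correlation and the block). Less the median of all genes, their median was 0.04, -0.00 and -0.91 in replicate numbers 1, 2 and 3, with 19, 22 and 44 lower, so the lower values lay in number 3. The remaining 15 lists did not pass by camera without the block. With it antioxidant enzymes (adjusted p = 0.0951, with the block 0.00992; 0.331 with an estimated correlation and the block) and unfolded protein and amino acid stress genes (adjusted p = 0.112, with the block 0.0211; 0.667 with an estimated correlation and the block) passed. The medians of mitochondrially encoded genes, annulus markers and nucleus pulposus markers changed from lower to higher after median-ratio scaling, and lay above the median of all genes both times. Under quantile normalization, however, mitochondrially encoded genes had a median of -0.26, or -0.23 less the median of all genes.

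Over 12019 genes limma called 24 rising and 3 falling (1632 at an unadjusted p under 0.05), and 218 and 233 with the block, or 243 and 79 with block and median-ratio scaling, which moved the median of all genes from -0.12 to -0.01. The groups did not overlap in 2657 genes, 22.1% against 10% by chance for exchangeable libraries and 2.25% to 4.54% in the other 3 splits that part every pair. The IL-17 signaling pathway held 8 of the 22 annotated risen genes (expected 0.130, Fisher exact test, adjusted p = 5.8e-10) and the TNF signaling pathway 8 (expected 0.180, adjusted p = 4.2e-09). In all 20 terms passed, and with the block 30 for rising and 6 for falling genes. The count of 27 became 8 and 12 without NC replicates 1 and 2, 42 without NC replicate 3, and 4 and 8 without OE_TNF replicates 1 and 2. The blocked count of 451 became 24, 42 and 1152 without replicate numbers 1, 2 and 3.

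At transcript level limma called 26 transcripts rising and 7 falling with TNF-α (86 and 63 with the block), 3 and 3 with CBX4 (2 and 2) and 21 and 5 in OE_TNF against NC (47 and 11). The 1 annotated Cbx4 transcript carried the values of the gene. Clip2, a microtubule-binding protein gene on chromosome 12 chosen after its values were seen, had 2 annotated transcripts of 17 exons each whose values alternated between libraries. ENSRNOT00000033200 lay at 19.0, 24.9 and 31.2 FPKM in OE_TNF and at 0.419, 0.383 and 0.379 in NC_TNF. ENSRNOT00000091328 had 28.0, 30.8 and 44.5 FPKM in NC_TNF and was listed at 0 in OE_TNF. In NC the first had 30.8, 0.129 and 0.670 FPKM and the second 0, 33.5 and 43.1.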

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

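The combinations with the block, the fits without genes listed at 0 the library left out for transcripts, and the block for transcripts, terms and the authors' calls were chosen after the data were seen, and the cause of a change was not tested unless given.

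Of the named-gene results under alternatives 3251 kept their side of the threshold, 247 came to pass, 125 no longer passed and 0 reversed. The 3251 include any change of sign within the SE of the main fit where neither fit passed. The other 4 changed sign by more than that SE, with no call in either fit. Of the list results 1665 kept their side of the threshold, 75 came to pass and 123 no longer passed. The 1665 include any change of direction where neither fit passed.

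For TNF-α in control cells the 24 called genes became 40 with all groups in the fit, 697 with the replicate block, 384 with library weights, 332 with all groups and block, 677 with median-ratio scaling and block, and 84, 59 and 863 with the block and number 1, 2 or 3 left out. Leaving out 1 library gave 0 (without NC_TNF replicate 1, 515 at an unadjusted p under 0.05 by limma) to 21 (without NC replicate 3), with 14 without NC replicate 1, 8 without NC replicate 2 and 9 without NC_TNF replicate 2.

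For CBX4 under TNF-α the 2 called genes became 0 with a pseudocount of 0.1, 0 with a mean FPKM of at least 5, and 0 without genes listed at 0 (1051 at an unadjusted p under 0.05 by limma). They became 174 with the block, 6 with library weights, 1265 with all groups and block, 24 with median-ratio scaling and block, and 1, 41 and 18 with the block and number 1, 2 or 3 left out. Leaving out 1 library gave 0 (NC_TNF replicate 1, OE_TNF replicates 1 and 2) to 5 (NC_TNF replicate 2, OE_TNF replicate 3), and 1 without NC_TNF replicate 3.

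For OE_TNF against NC the 27 called genes became 85 with all groups in the fit, 451 with the block, 564 with library weights, 2256 with all groups and block, 322 with median-ratio scaling and block, and 24, 42 and 1152 with the block and number 1, 2 or 3 left out, against 451 with the block and all numbers. Leaving out 1 library gave 4 (OE_TNF replicate 1) to 42 (NC replicate 3), with 8 without NC replicate 1, 12 without NC replicate 2 and 8 without OE_TNF replicate 2.

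The 1 opposed gene became 0 with a pseudocount of 0.1, 0 with a mean FPKM of at least 5 and 0 without genes listed at 0. It became 12 with the block, 37 with all groups and block, 2 with median-ratio scaling and block, and 0 and 2 with the block and number 1 or 2 left out, and 0 to 1 with 1 library left out (0 without any NC_TNF library or OE_TNF replicates 1 and 2).

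With an estimated correlation cytokines and chemokines (NC_TNF against NC) had an adjusted p of 0.0503, fibrous matrix 0.187 and cell cycle genes (OE_TNF against NC_TNF) 0.484. With 1 library left out the camera adjusted p ranged from 1.8e-32 to 2.6e-23, from 7.0e-10 to 0.000730 and from 5.2e-17 to 8.8e-08 for these lists.

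With the block 149 transcripts passed for NC_TNF against NC and 58 for OE_TNF against NC. Leaving out 1 library gave 8 to 22, 4 to 13 and 6 to 29 transcripts in the order of the comparisons. Terms came to 113, 31 and 36 with the block, and 194 and 78 of the authors' calls were shared.

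No alternative on read counts was run, since the tables hold none. Camera was not run with library weights or a fold threshold.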

Other observations

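The tests of the NC_TNF libraries, of single replicate pairs and of genes listed at 0 across groups were chosen after the result was seen.

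Some genes of glutathione handling and of the proteasome, which limit oxidative and protein damage, fell with CBX4 under TNF-α in the blocked fit without scaling. Glutathione metabolism held 6 of the 141 annotated fallen genes (43 tested, expected 0.544, one-sided Fisher exact test, adjusted p = 0.00550) and Proteasome 7 (44 tested, expected 0.557, Fisher exact test, adjusted p = 0.000654). The members of a term were not examined one by one, so the 6 need not all act in glutathione handling. Gsta1, a glutathione transferase gene, changed by -1.80 (blocked adjusted p = 0.0380, unblocked 0.543) and Gsr, the glutathione reductase gene, by -1.19 (blocked 0.0483). Both were chosen after their values were seen. Of the 142 genes that fell with the block, median-ratio scaling left 9 passing. Changes were smaller after it, and a smaller p-value was needed to pass. Gsr no longer passed at an unadjusted limma p of 0.00055, while before scaling Rfc5, chosen after its values were seen, passed at 0.00072. How far smaller changes and the adjustment each contributed was not tested. The proteasome genes Psma1 (-1.02, then -0.89, SE 0.14 and 0.13, adjusted p = 0.0702) and Psmd3 (-0.88, then -0.75, SE 0.12 and 0.11, adjusted p = 0.0706), chosen after their values were seen, kept most of their change. Gsta1 was among the 9 (-1.68, SE 0.14, before 0.13, adjusted p = 0.0474) and Gsr was not (-1.07, SE 0.14, before 0.15, adjusted p = 0.0702). Of 24 antioxidant enzymes 18 were lower, with a median of -0.33, or -0.20 after median-ratio scaling.

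All 44 cell cycle genes were lower with CBX4 under TNF-α, by a median of -0.84. Library scaling as the whole source is argued against, since the median stayed at -0.7337 after median-ratio scaling, although the number called with the block went from 23 to 2. A single replicate pair as the source is argued against, since the highest of the 3 pair medians less all genes was -0.6674. High NC_TNF libraries may be the source in numbers 1 and 2, where OE_TNF against NC gave pair medians less all genes of 0.03595 and -0.0038, but in number 3 NC_TNF (3.67) lay below NC (4.08) and OE_TNF against NC gave -0.905, which goes against it for that pair. An effect of CBX4 stays open as well, without a group of CBX4 alone to test it.

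More genes fell than rose with CBX4 in the blocked fit, 142 against 32. After median-ratio scaling 37.5% of the called genes fell, against 81.6% before. All 142 genes stayed lower, with a median change of -0.89 before and -0.76 after (median SE 0.11 and 0.10) and no adjusted p above 0.0858. The share thus changed through genes near the threshold, and how far the scale of the libraries made the excess is left open. No biological explanation was tested.

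Of 61 genes at 4 FPKM or more in some libraries and at most 0.1 in others, 96.72% had zeros that cut across the groups, so estimates that fail per library may account for most of them. The zeros of 2 followed the groups, against 0.679 expected from random libraries. These were Wdr77 and LOC100911917, the latter chosen after its values were seen, at 4.73, 4.27 and 7.84 FPKM in OE_TNF and listed at 0 in the other libraries. Gns was not among them, with zeros in 2 of 3 NC_TNF libraries. Failing estimates and an effect of treatment cannot be told apart for this pair, since the tables hold no reads.

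The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. For NC_TNF against NC the real split called 24 genes and 1 of the 10 splits gave as many, with 17 in the highest other, which put NC replicate 1 with NC_TNF replicates 1 and 3 and parted 1 pair. For OE_TNF against NC_TNF 2 splits gave as many as the real 2, with 4 in the highest other, which put OE_TNF replicate 3 with NC_TNF replicates 1 and 3. For OE_TNF against NC 1 split gave as many as the real 27, with 3 in the highest other. For transcripts 1, 3 and 1 splits gave as many as the real 33, 6 and 26, with 21, 13 and 7 in the highest others. Of the 4 splits that part all 3 pairs, the highest other called 3, 1 and 2 genes without the block, and 1, 1 and 4 with it against the real 697, 174 and 451. The other splits swap the sides of a pair, so any real effect enters the spread and lowers their counts. Their low counts are thus partly built in and are no test of the blocked counts.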
